A study of Homo sapiens with 14 samples.

How the data were processed

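Gene expression was measured in total RNA on 14 Illumina BeadChip arrays with biotin-labelled amplified RNA, from 2 prostate cancer cell lines. Each line had 3 arrays of cells given 50 µM dilazep for 48 h, 2 arrays of cells given water (H2O) and 2 arrays of cells given DMSO, which makes 6 groups. Replicates are numbered as in the sample titles. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels do not say which of the 2 vehicles belongs to dilazep, and both control groups were given equal weight. The treatment text of the control arrays names another compound, bufalin, whose arrays were not analysed here. The controls may therefore belong to a separate experiment, and each change with dilazep would then also hold any difference between the experiments. The dilazep arrays carry no sample number of the kind the control arrays carry, and no label names a chip or a run, so neither could be used as a block.

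The main table deposited by the authors holds a linear signal intensity per probe and array, with no background subtraction or scaling that the values show, and beside each intensity a detection p-value, as named per the file headers. It lists 47422 probes, of which 99 are second listings with identical values, so that 47323 are distinct. Median signals lay between 144.6 and 154.6 per array, and 17925 to 19856 probes per array (37.9% to 42.0%) had a detection p-value under 0.05. A second table deposited by the authors holds processed values of 22912 of these probes on a log2 scale, and the submitters' processing notes name lumi with no version. The exact transform, normalization and filter behind it are not given in the sources used here. Its array medians all came to 8.02, its slope on log2 signal was 1.02 above a log2 signal of 12 and 0.570 below 7.5, and 14 of 14 arrays were best matched by their own processed column. That table is on a log2-like scale that flattens at low signals, was not centred per gene, and was used as an alternative only. Columns were matched to samples by the titles in the table's header, because a second line of sample numbers in that header differs from some sample descriptions.

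Probes were named from the platform annotation, with symbols brought up to date through Entrez identifiers. Of the 22912 processed probes, 16501 had 1 gene symbol, 5 had several and 6406 were unnamed here. Probes without a single symbol were left out of the tests and counted separately. Signals were background corrected with normexp, using negative control levels inferred from the detection p-values, then quantile normalized and log2 transformed (neqc in limma 3.58.1 under R 4.3.3, offset 16). A probe was kept where its detection p-value was under 0.05 on at least 2 arrays, which left 24894 probes. Each gene was represented by its kept probe with the highest mean level, which gave 11983 genes, 3145 of them with 2 or more kept probes. Where another probe of a gene named for dilazep or between the lines gave a different call, or a change that differed by more than 1.5 times, this is said in the same paragraph. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

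A linear model with 1 mean per group was fitted to all 14 arrays with lmFit, and 5 contrasts were tested two-sided with eBayes. They were dilazep against the mean of the H2O and DMSO means in LNCaP, the same in LNCaP-abl, the difference between these responses, LNCaP-abl against LNCaP controls, and DMSO against H2O averaged over both lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p printed for a gene comes from this limma fit. Changes are differences of mean log2 values with their standard error (SE), over 3 dilazep and 4 control arrays per line. Where no array of a group had a detection p-value under 0.05 for the gene, the gene had only a bound in that group. The fold is then given as "at least N-fold", from the mean of the brighter group and, per array of the dimmer group, the higher of the gene's own level and the lowest level among detected probes.

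Before the data were examined, 24 gene lists and the rule for naming genes were fixed from textbook knowledge. The lists were GATA2 and its prostate partners, androgen-induced genes, androgen-repressed genes, G1/S and DNA replication, G2/M and mitosis, cholesterol synthesis and uptake, fatty acid synthesis, the ATF4 integrated stress response, the unfolded protein response of the endoplasmic reticulum (ER), p53 targets, hypoxia response and glycolysis, lysosome and autophagy, adenosine transport and signalling, MYC targets and ribosome biogenesis, oxidative phosphorylation, interferon response, heat shock proteins, and calcium channels and signalling. The others were markers of neuroendocrine, luminal epithelial, basal or mesenchymal, fibroblast, immune and endothelial cells. Some genes belong to several lists, so the lists are not independent of each other. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists of a comparison, and again with an estimated correlation. The estimated version also takes its p from the 8 residual degrees of freedom of the fit, which by itself makes it stricter. A call lost there need not reflect correlation between members. The fry test was run in addition. It asks whether a list moves on balance one way, or changes in either direction, without setting it against other genes. Named genes were the 8 largest rises and 8 largest falls of each comparison among called genes whose arrays did not overlap (6 and 6 for the difference of responses), 11 genes in every comparison whether called or not, and up to 4 members per list with the smallest p. Of the 11 genes, GATA2, FOXA1, HOXB13, KLK3, KLK2, TMPRSS2, IGF2, SLC29A1 and SLC29A2 are given, and the others are not reported here.

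The method was tested on simulated data for these 11983 genes. A log2 change of 1 was recovered for 86.6% of changed genes in the LNCaP comparison, 94.0% in the LNCaP-abl comparison, 68.7% in the difference of responses, 91.0% between the lines and 91.0% between the vehicles. A log2 change of 0.5 was recovered for 49.3%, 43.3%, 11.9%, 43.3% and 41.8% in the same order. False calls numbered 8 to 11 per comparison. Each simulation changed only 67, 67 and 66 genes by 0.5, 1 and 2, with noise independent between genes. Far more genes were called in the real dilazep and line comparisons, where the same threshold lets more false calls pass. The simulated counts and shares therefore do not carry over to those comparisons. Between the vehicles, where 0 genes were called, the cut-off for a single gene was stricter than in the simulation. The number of arrays limits the precision.

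Arrays of a group were compared before averaging. The SD of the difference between 2 arrays of a group was 0.28 to 0.37 on the log2 scale, at most 0.289% of probes had equal signals, and no array was a copy of another. Alternatives were the authors' processed values, no background correction, median scaling, no filter and a stricter filter (detection p-value under 0.01 on every array), the mean of a gene's probes or all probes tested individually, trended and robust eBayes, array weights, only the arrays of a comparison, the vehicles merged or each alone, the replicate number as a block, a minimum log2 change of 1, and each array left out in turn. A call counted as the same where its direction and its side of the threshold were the same, a gene or list called in neither setting also counted as the same, and a count of calls counted as the same within 1.5 times.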

Results

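Expression was profiled in LNCaP, an androgen-sensitive human prostate cancer line grown in 10% fetal bovine serum, and in LNCaP-abl, a subline of LNCaP adapted to androgen deprivation and grown in 10% charcoal-stripped serum. Cells received 50 µM dilazep, a vasodilator that blocks cellular uptake of adenosine, or a control (H2O or DMSO) for 48 h. The series was set up to target GATA2, a transcription factor of prostate cells, with dilazep. There were 3 dilazep arrays, 2 H2O arrays and 2 DMSO arrays per line. The labels of the controls name another compound, bufalin, so it is open whether they were treated in the same experiment as the dilazep cells. Between 17925 and 19856 probes were detected per array, and 11983 genes were tested. In a principal component analysis of the 14 arrays, the first component (51.6% of the variance) parted the lines and the second (29.4%) parted dilazep from control arrays in both lines. The first also moved with dilazep, from at most 27.2 to at least 57.3 in LNCaP-abl and from at most -44.1 to at least -34.5 in LNCaP. On the third (7.92%), dilazep and control arrays lay apart in opposite directions in the lines. LNCaP controls lay at 14.6 to 19.7, and LNCaP dilazep arrays between -13.2 (replicate 1) and -28.9 (replicate 4). LNCaP-abl controls lay between the DMSO arrays at -2.19 (replicate 1) and -16.5 (replicate 3), and LNCaP-abl dilazep arrays at 11.6 to 12.9.

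In LNCaP, dilazep was followed by a rise of sterol synthesis genes and a fall of mitotic genes, while GATA2 itself was not called. HMGCS1, which makes the precursor of mevalonate, rose by a log2 change of 3.34 (SE 0.10, adjusted p = 1.4e-09), from means of 10.31 ± 0.11 (SD, n = 2) with H2O and 10.27 ± 0.18 (n = 2) with DMSO to 13.63 ± 0.06 (n = 3). The largest rise was that of ANGPT2, a vascular growth factor, at 4.40 (SE 0.13, adjusted p = 1.4e-09). Other large rises were those of DIO3 (2.93), which inactivates thyroid hormone, the zinc transporter SLC30A4 (2.84), the glycolytic enzyme ENO2 (2.80), ID1 (2.36), and the sterol enzymes MVD (2.36) and LSS (2.26). A second probe of ID1 gave 0.32 and was not called, while other probes gave 2.77 and 3.98 for ANGPT2 and 0.87 and 1.12 for LSS. Among the largest falls were TM4SF1, a membrane protein of the tetraspanin type (-3.64, SE 0.13), the prostate secretory protein gene MSMB (-3.21, SE 0.16) and the neuropeptide gene NMU (-3.11, SE 0.08, adjusted p = 5.7e-10). RNLS was at least 8.66-fold lower, with no dilazep array above background, and its other probes gave -2.52 and -0.31. TRIM49D1 (-4.22), TRIM49D2 (-3.78) and TRIM49C (-3.03) fell too, as did the pseudogene GRM5P1 (-3.08). The TRIM49 genes are near-identical copies, so which of them changed is uncertain. In all, 5261 genes were called, 2899 higher and 2362 lower, of which 866 changed by at least 1 on the log2 scale. With median scaling the share of higher calls was 62.8% in place of 55.1%.

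Of GATA2 and the prostate genes named in every comparison, GATA2 changed by 0.06 (SE 0.10, adjusted p = 0.662) in LNCaP, HOXB13 by 0.11, KLK3, which encodes prostate-specific antigen, by -0.34 (adjusted p = 0.133), KLK2 by -0.06, TMPRSS2 by 0.21 and FOXA1 by -0.02, none of them called. The adenosine transporter gene SLC29A2 rose by 0.62 (SE 0.10, adjusted p = 4.3e-04), and IGF2 and SLC29A1 were not called. The wider list of androgen-induced genes fell. Of its 37 measured members, 21 fell and 4 rose, with the same counts adjusted over the list alone (median -0.34, adjusted p = 4.7e-05 for the list). TRPM8, a cation channel (-3.00), the lipid phosphatase gene PLPP1 (-1.93), STK39 (-1.20) and the drug exporter ABCC4 (-0.95) had the smallest p among them. Of 13 measured androgen-repressed genes, 7 fell and 2 rose, also adjusted over the list alone (median -0.82, adjusted p = 0.0146). That list's call was lost at adjusted p = 0.115 with an estimated correlation, and its median was -1.41 with the stricter detection filter, -1.49 with the replicate block and -1.43 without dilazep replicate 4. CLDN8 (-2.17) and the steroid-conjugating enzymes UGT2B28 (-1.84) and UGT2B11 (-1.44) were among its members that fell. The list holds several UGT2B genes of the same family, counted as separate members. Whether their probes tell them apart was not tested. Of the 9 measured members of the list of GATA2 and its prostate partners, 3 fell, also adjusted over the list alone, and none rose (adjusted p = 0.172). They were CREB3L4 (-1.41), MYC (-0.77) and FOXM1 (-1.19). MYC also belongs to the list of MYC targets, and FOXM1 to the G2/M list. Other probes gave -1.20 for MYC and -1.74 for TRPM8.

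Mitotic genes fell nearly throughout in LNCaP. Of the 44 measured G2/M genes, 42 fell and 0 rose, the same counts adjusted over the list alone (median -1.34, adjusted p = 1.1e-27). PTTG1, which encodes securin, fell by 2.00 on the log2 scale (SE 0.07), the mitotic kinesin gene KIF20A by 1.91 and cyclin A2 (CCNA2) by 1.92. Of 34 G1/S and DNA replication genes, 21 fell and 0 rose, adjusted over the list alone as well (median -0.46, adjusted p = 1.5e-07), among them RFC3 (-1.51, with other probes from -2.51 to -0.56), TYMS (-1.37) and RRM2 (-1.61). Of 37 MYC targets and ribosome biogenesis genes, 19 fell and 2 rose (20 and 2 adjusted over the list alone, median -0.30, adjusted p = 1.2e-05), including POLR3G (-1.22), NOLC1 (-0.89) and DDX21 (-1.16).

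Lipid and lysosomal genes rose in LNCaP. Of 24 genes of cholesterol synthesis and uptake, 19 rose and 2 fell (20 and 2 adjusted over the list alone, median 1.10, adjusted p = 1.8e-09), with FDPS at 2.15 (SE 0.08) and TM7SF2 at 1.77 (SE 0.08). Of 18 fatty acid synthesis genes, 12 rose and 1 fell, as adjusted over the list alone (median 0.64, adjusted p = 6.6e-05). The acetyl-CoA synthetase gene ACSS2 (1.96, with other probes at 0.99 and 2.00), ACSL1 (1.78), FADS2 (1.39) and the desaturase gene SCD (1.27) were examples. Of 36 lysosome and autophagy genes, 27 rose and 2 fell, as adjusted over the list alone (median 0.55, adjusted p = 5.6e-07), among them the sialidase gene NEU1 (1.80), the cholesterol carrier NPC2 (1.52) and the autophagy receptor SQSTM1 (1.51). With an estimated correlation, 7 of the 8 called lists kept their call in LNCaP, all but the androgen-repressed genes. The other 16 lists were not called, with adjusted p from 0.0802 to 0.964. No label names a chip or run, so neither could be used as a block, and with the replicate number as a block 3237 genes were called. That block takes dilazep replicate 4, the only LNCaP array with its number, out of the LNCaP comparison. With the authors' processed values, which flatten low signals, 50 of the 102 called named genes had a log2 change that differed by more than 1.5 times (median ratio 0.668), and the medians of the androgen-induced and lysosome lists were -0.16 and 0.30.

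In LNCaP-abl, dilazep was followed by a fall of cell cycle genes, a rise of sterol and ATF4 stress genes, and a fall of GATA2. GATA2 fell by 0.93 on the log2 scale (SE 0.10, adjusted p = 9.9e-06), from means of 8.84 ± 0.22 (SD, n = 2) with H2O and 8.88 ± 0.14 (n = 2) with DMSO to 7.93 ± 0.02 (n = 3). HOXB13, a prostate homeobox factor, changed by -1.15 (SE 0.12, adjusted p = 5.9e-06) and KLK2 by -2.39 (SE 0.17, adjusted p = 2.9e-07). KLK3 was at least 2.14-fold lower, with none of the 3 dilazep arrays above background (adjusted p = 9.1e-06). TMPRSS2, an androgen-driven protease gene, rose by 0.62 (SE 0.11, adjusted p = 5.1e-04). FOXA1 rose by 0.31 (adjusted p = 0.0089), a call that was lost with median scaling (0.17, adjusted p = 0.158) and against DMSO alone (0.25, adjusted p = 0.0592). SLC29A2 (0.11), IGF2 and SLC29A1 were not called.

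**Figure D1:**
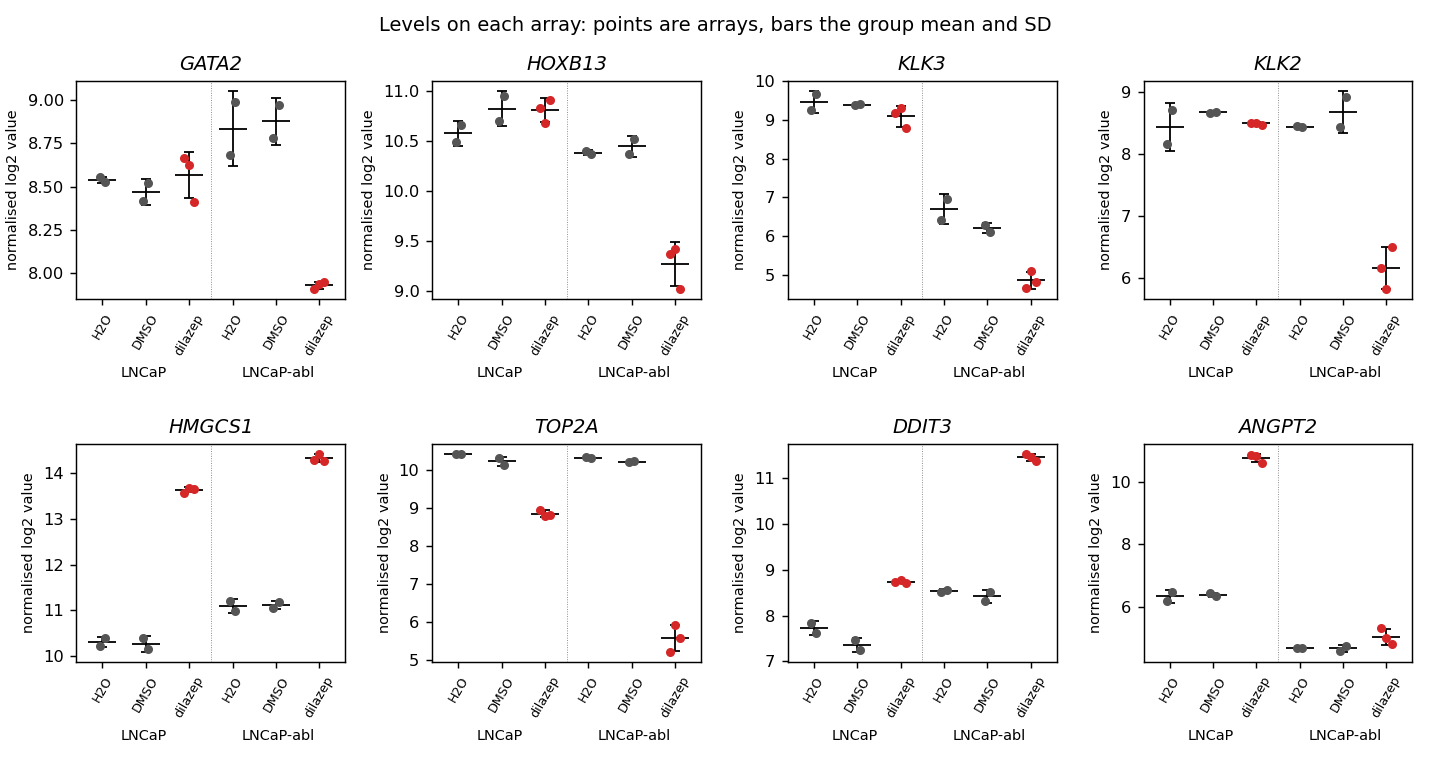
Log2 level of 8 genes on each of the 14 arrays, by cell line and treatment, with 1 point per array and bars for the group mean and SD. GATA2 lies at 7.93 on average in LNCaP-abl with dilazep and at 8.57 in LNCaP with dilazep, and KLK3 in LNCaP-abl with dilazep was not above background.

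The largest falls in LNCaP-abl, by the probe that stood for each gene, were all in genes of DNA replication and cell division. CDC45, part of the replicative helicase, was at least 28.5-fold lower and the mitotic kinase gene AURKB at least 18.8-fold lower, both not above background with dilazep. NCAPG, a condensin subunit, changed by -5.02 (SE 0.12, adjusted p = 3.2e-11), CDCA3 by -4.71, topoisomerase TOP2A by -4.68, MCM10 by -4.62, CEP55 by -4.55 and UBE2C by -4.48. The other probe gave -2.76 for MCM10 and -0.51 for UBE2C. Of the 44 G2/M genes, 44 fell, also adjusted over the list alone (median -3.40, adjusted p = 8.5e-36), and the median was -3.39 with the 8 members that had only a bound set to it. Of 34 G1/S genes, 32 fell and 0 rose, as adjusted over the list alone (median -2.53, or -2.44 with 8 members at their bound, adjusted p = 4.4e-23), with GINS2 at -4.21 (SE 0.10). Of 37 MYC targets and ribosome biogenesis genes, 33 fell and 0 rose, also over the list alone (median -0.94, adjusted p = 4.0e-14). MYC itself changed by -2.05 (SE 0.11), LYAR by -1.72 and the nucleolar methyltransferase gene FBL by -1.28.

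By the probe that stood for each gene, the largest rises in LNCaP-abl were TMEM140 (4.15, SE 0.12), the chemokine gene CCL20 (3.87, SE 0.11, adjusted p = 1.2e-10) and SDCBP2 (3.53, with other probes from -0.15 to 2.12). MMP10, a matrix metalloproteinase gene, was at least 7.83-fold higher, with no control array above background. ID1 (3.41), the sterol enzyme SC5D (3.27), HMGCS1 (3.21, SE 0.10, adjusted p = 1.5e-10) and the immediate early gene EGR1 (3.10) followed. The other probe of ID1 gave 0.97. Another probe of CXCL8, a chemokine gene with 2.45 at its own, gave 4.44. Of 36 ATF4 integrated stress response genes, 30 rose and 0 fell (33 and 0 adjusted over the list alone, median 0.99, adjusted p = 4.6e-12). The transcription factors DDIT3 (2.98, SE 0.09) and ATF3 (2.91, SE 0.09), PCK2 (1.92) and asparagine synthetase ASNS (1.79) were examples. Of 24 cholesterol genes, 18 rose and 2 fell (18 and 3 adjusted over the list alone, median 1.23, adjusted p = 1.3e-07), with TM7SF2 at 2.49 and IDI1 at 2.44. Of 36 lysosome and autophagy genes, 24 rose and 0 fell, also over the list alone (median 0.62, adjusted p = 8.1e-08), with NEU1 at 2.77, the cholesterol exporter NPC1 at 1.73 and MAP1LC3B at 1.76. Of 18 fatty acid genes, 12 rose and 0 fell, as adjusted over the list alone (median 0.55, adjusted p = 4.9e-04), with ACSS2 at 1.78 and malic enzyme ME1 at 1.45.

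Both lists of hormone-regulated genes were called lower in LNCaP-abl, and neither call held with an estimated correlation. Of 37 androgen-induced genes, 17 fell and 5 rose (18 and 5 adjusted over the list alone, median -0.23, adjusted p = 0.00615). That call was lost at adjusted p = 0.0743 with an estimated correlation and at 0.166 with the stricter detection filter. The list's median ran from -0.40 with median scaling to -0.08 with that filter, with -0.10 from the authors' processed values, -0.12 without background correction and -0.15 against H2O alone. TRPM8 changed by -3.14 (-1.86 at its other probe) and NCAPD3 by -1.99. Of 13 androgen-repressed genes, 8 fell and 3 rose, as adjusted over the list alone (median -1.02, adjusted p = 0.00805, and adjusted p = 0.0834 with an estimated correlation, or median -2.33 with the stricter filter), with UGT2B10 at -2.49 and UGT2B17 at -2.14. The UGT2B genes again count as separate members of the list. Of the 9 members of the list of GATA2 and its partners, 5 fell and 2 rose, also over the list alone, and the list missed the threshold (median -0.93, adjusted p = 0.0506). It had an adjusted p = 0.104 with an estimated correlation. That correlation was -0.016, below the preset 0.01, so correlation between members does not account for the larger adjusted p. The list was called under 15 of 30 alternatives, among them each vehicle alone (adjusted p = 0.0390 with H2O and 0.0429 with DMSO) and no background correction (adjusted p = 0.0326). Those 15 calls include both fry tests, which set no list against other genes. Among the members that fell were FOXM1 (-3.27), also in the G2/M list, and MYC (-2.05), also in the MYC list. The list without these shared members was not tested. In all, 6049 genes were called in LNCaP-abl, 3261 higher and 2788 lower, of which 1447 changed by at least 1 on the log2 scale. With median scaling the share of higher calls was 37.8% in place of 53.9%, and with the authors' processed values 48 of the 103 called named genes had a log2 change that differed by more than 1.5 times (median ratio 0.677). With those values the list medians were -2.00 for G2/M, -1.48 for G1/S and 0.80 for cholesterol genes, and with median scaling that of the lysosome list was 0.41. With an estimated correlation, 7 of the 9 called lists kept their call, and the other 15 lists were not called in the first place (adjusted p from 0.0506 to 0.801).

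**Figure D2:**
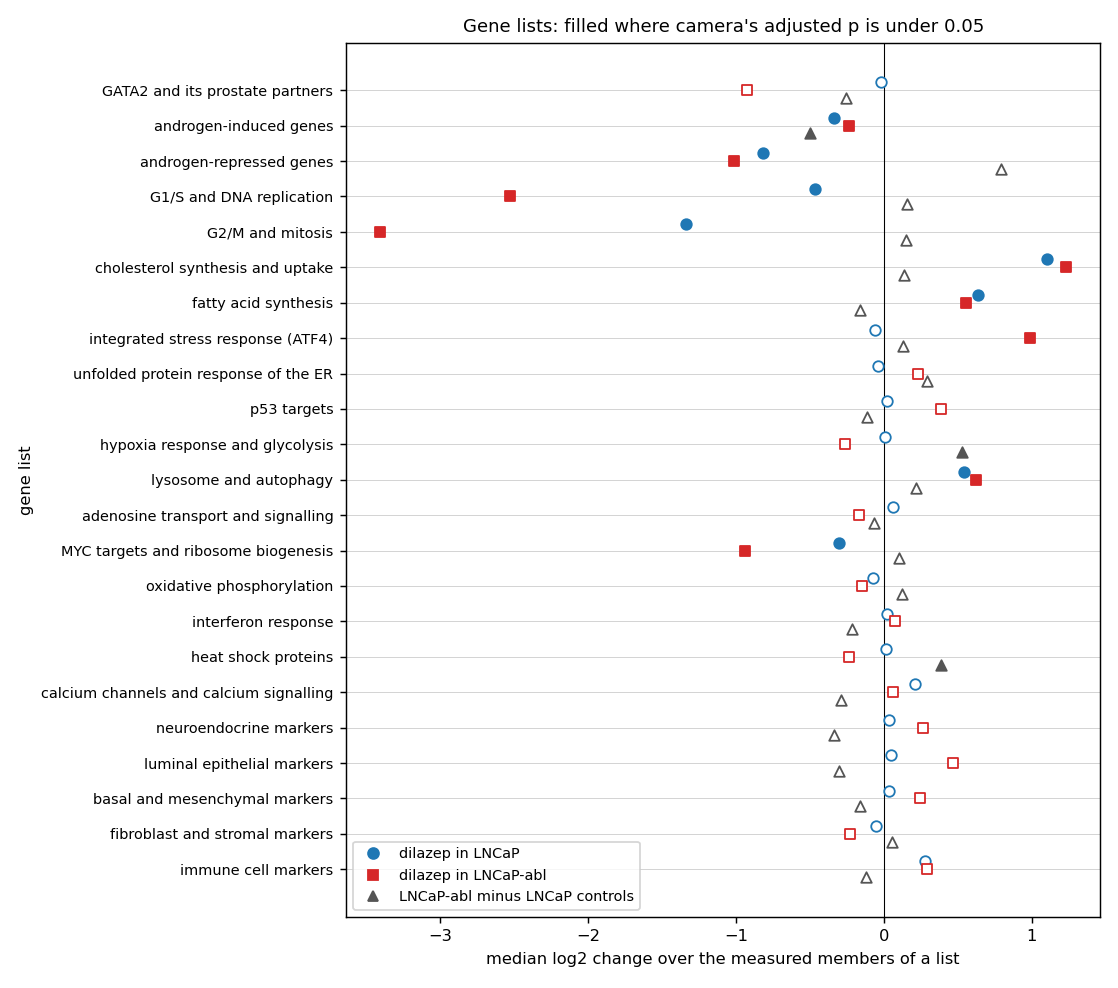
Median log2 change of each gene list with dilazep in LNCaP (circles) and in LNCaP-abl (squares) and between the controls of the lines (triangles), filled where the list was called, leaving out the endothelial list, which had 1 measured member. The G2/M list lies at -1.34 in LNCaP and -3.40 in LNCaP-abl, and the ATF4 stress list at -0.06 and 0.99.

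The difference between the responses of the lines was tested for each gene. The ATF4 stress genes and the cell cycle genes stood furthest apart. Of the 36 stress genes, 32 had a more positive response in LNCaP-abl and 0 a more negative one (33 and 0 adjusted over the list alone, median difference 1.01, adjusted p = 6.9e-20). The cystine transporter gene SLC7A11 differed by 3.55 (SE 0.27, adjusted p = 2.1e-06), with changes of 2.60 in LNCaP-abl and -0.95 in LNCaP, and CTH differed by 2.97 (1.21 and 1.92 at other probes) and ATF3 by 2.27. CHAC1 differed by 2.78 and SLC7A5, an amino acid transporter gene, by 1.63, both with a level in LNCaP with dilazep that was not above background. The G2/M list had 42 more negative and 0 more positive responses in LNCaP-abl (43 and 0 adjusted over the list alone, median -2.09, adjusted p = 2.1e-32) and the G1/S list 30 and 0, also over the list alone (median -2.08, adjusted p = 1.8e-24). MCM10 differed by -4.14 (SE 0.17, adjusted p = 4.3e-08), NCAPG by -3.77, GINS2 by -3.52, TK1 by -3.48, CDCA3 by -3.32, TTK by -2.58 and CDC20 by -2.56. For DTL (-3.96), AURKB (-3.88) and CDC45 (-3.85) the level in LNCaP-abl with dilazep was not above background, so these differences rest on a bound. UBE2C differed by -2.80, but its other probe gave 0.08 and was not called, and the other probe of MCM10 gave -1.31. MYC targets and ribosome biogenesis genes had 26 more negative and 0 more positive responses (29 and 0 adjusted over the list alone, median -0.70, adjusted p = 3.0e-08). PA2G4 (-1.02), BOP1 (-0.97), FBL (-0.97) and MYC (-1.28, with -0.46 at its other probe, not called) were examples. With the authors' processed values the median differences were -0.90 for G2/M, -1.14 for G1/S and -0.39 for MYC targets, and without background correction they were -1.19 for G2/M and -1.28 for G1/S. The ATF4, G2/M, G1/S and MYC lists kept their call with an estimated correlation, and the other 20 lists were not called (adjusted p from 0.0725 to 0.945).

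The fall of GATA2 in LNCaP-abl differed from its change in LNCaP by -0.99 (SE 0.14, adjusted p = 3.2e-04). The response of HOXB13 differed by -1.26 (adjusted p = 1.7e-04) and that of KLK2 by -2.33 (adjusted p = 3.0e-05). KLK3, with only a bound in LNCaP-abl, differed by -1.25 (adjusted p = 0.0022), a call lost with the authors' processed values (-0.09, adjusted p = 0.620) and without background correction (-0.29, adjusted p = 0.119). SLC29A2 differed by -0.51 (adjusted p = 0.0161), and lost its call against DMSO alone (adjusted p = 0.0796) and with the replicate block (adjusted p = 0.106). FOXA1 (0.32, adjusted p = 0.0535) and TMPRSS2 (0.41, adjusted p = 0.0617) missed the threshold, and IGF2 and SLC29A1 were not called. ANGPT2, which rose in LNCaP and was not above background in LNCaP-abl, differed by -4.04. MMP10 (3.85) and CCL20 (3.79) were not above background in LNCaP with dilazep, nor was MMP10 in LNCaP-abl controls or CCL20 in LNCaP controls, so these differences rest on a bound. TRIM49D1 (4.00), TRIM49D2 (3.91) and TRIM49C (3.61) fell in LNCaP and had changes of -0.22, 0.13 and 0.58 in LNCaP-abl, where TRIM49D2 was not above background.

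In all, 4056 genes had a response that differed between the lines, 1907 more positive and 2149 more negative in LNCaP-abl, and 1182 of the differences were at least 1 on the log2 scale. With median scaling 22.7% in place of 47.0% were more positive, while that scaling moved the median difference of all genes to -0.22, and with the replicate block 2302 genes were called. The log2 difference of 52 of the 96 called named genes moved by more than 1.5 times with the authors' processed values (median ratio 0.654). The responses of the lines, which share no arrays, had 1621 genes higher in both and 1318 lower in both, where independent lists would share 789 and 550. Another 165 genes were higher in LNCaP and lower in LNCaP-abl and 226 the reverse, where independent lists would share 674 and 643. All 391 were also called in the test of the difference. Opposite called changes add up in that test, so this was close to fixed in advance and is no further support. Across genes, which are not independent replicates, the 2 responses had a Pearson r of 0.548 and a Spearman rho of 0.499.

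**Figure D3:**
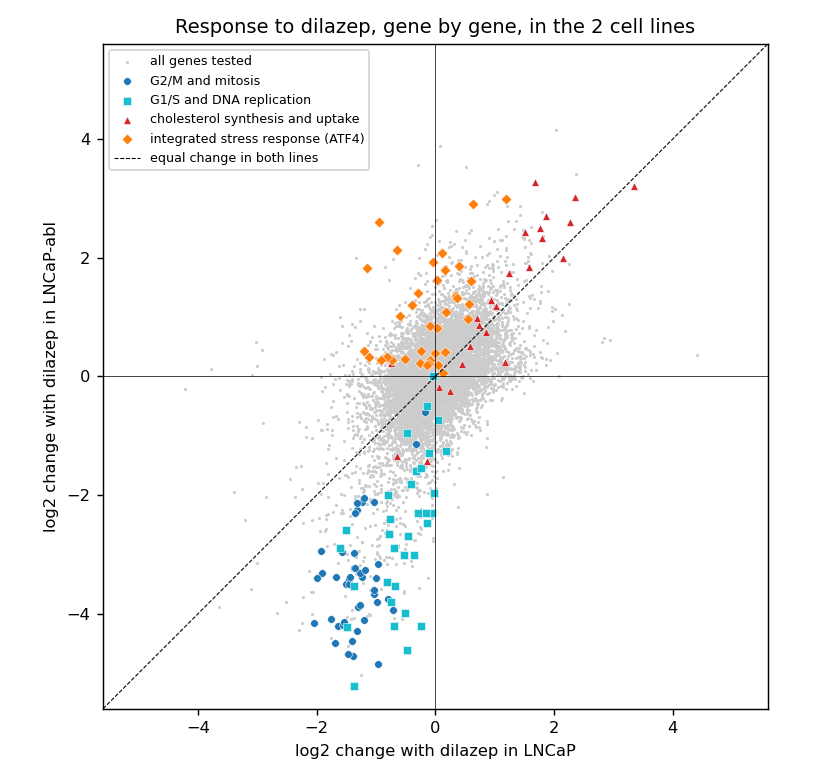
Log2 change with dilazep of each of the 11983 genes in LNCaP (horizontal) and LNCaP-abl (vertical), with the G2/M, G1/S, cholesterol and ATF4 stress lists coloured and a dashed line where both changes are equal. Most cell cycle genes lie below the line (median difference -2.09 for G2/M) and most ATF4 stress genes above it (median difference 1.01).

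Control arrays of LNCaP-abl and LNCaP were compared to describe the lines before dilazep. Line and serum changed together, so their shares cannot be told apart. OR51E2, a prostate olfactory receptor gene, was at least 201-fold higher in LNCaP-abl, and the cancer-testis genes CT45A3 and CTAG2 were at least 48.2-fold and 32.9-fold higher, all not above background in LNCaP. PAGE1, another cancer-testis gene, was higher by 5.71 (SE 0.12, adjusted p = 4.9e-12), and the cytokine gene IL32 by 5.51, EPHX4 by 5.37, HENMT1 by 5.26 and NDP by 5.25. Other probes gave 3.62 for IL32, 2.88 for CTAG2 and -1.99 for DSEL. EEF1A2, a translation elongation factor gene, differed by -7.07 (SE 0.13, adjusted p = 1.4e-12), BCHE by -6.07 and MARCKS by -5.35. TMEFF2 was at least 67.7-fold lower, TMEM205 57.4-fold, CBLN2 53.2-fold, DSEL 35.9-fold and RALYL 30.2-fold, with no LNCaP-abl control above background. KLK3 differed by -2.98 (SE 0.16, adjusted p = 1.9e-08), while KLK2 (0.00), TMPRSS2 (0.19), SLC29A2 (0.22), IGF2 and SLC29A1 were not called. GATA2 was higher by 0.35 (SE 0.09, adjusted p = 0.0078), with the call lost against H2O controls alone (adjusted p = 0.101). HOXB13 (-0.29, adjusted p = 0.0456) and FOXA1 (-0.21, adjusted p = 0.0385) lay close to the threshold and lost their call under several alternatives, among them median scaling (adjusted p = 0.151 and 0.109).

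Androgen-induced genes were lower in LNCaP-abl controls, with 23 of 37 lower and 9 higher, as adjusted over the list alone (median -0.50, adjusted p = 0.0162). The call was lost at adjusted p = 0.296 with an estimated correlation and at 0.159 with the stricter filter. AZGP1 was at least 23.3-fold lower, PMEPA1 changed by -4.30 (SE 0.15, with other probes at -3.99 and -0.93) and SLC45A3 by -1.53. Of 31 hypoxia response and glycolysis genes, 20 were higher and 3 lower, also over the list alone (median 0.53, adjusted p = 4.6e-04, and adjusted p = 0.316 with an estimated correlation), among them ENO2 (3.38), carbonic anhydrase CA12 (2.14, or 1.32 at its other probe), PFKP (1.32) and ALDOA (1.14). Of 21 heat shock protein genes, 16 were higher and 0 lower, as adjusted over the list alone (median 0.39, adjusted p = 1.1e-04, and adjusted p = 0.0420 with an estimated correlation). The small heat shock gene HSPB8 was at least 8.51-fold higher, CRYAB was higher by 2.66, DNAJB4 by 0.88 and HSPH1 by 0.74. In all, 5871 genes differed, 3006 higher and 2865 lower, 1235 of them by at least 1 on the log2 scale, and the other 21 lists were not called (adjusted p from 0.0624 to 0.864). With the authors' processed values, 59 of the 104 called named genes had a log2 difference that moved by more than 1.5 times (median ratio 0.632), and the medians of the androgen-induced and hypoxia lists were -0.26 and 0.27.

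DMSO and H2O controls were compared to see how far the 2 control groups differ. The treatment text of both names bufalin, so the comparison cannot show a difference in experiment or run between controls and dilazep arrays. Over both lines, limma called 0 of 11983 genes (smallest adjusted p = 0.758), and 532 genes had an unadjusted p under 0.05, where chance alone gives 599. Within LNCaP 0 genes were called and 634 had an unadjusted p under 0.05, and within LNCaP-abl these numbers were 0 and 431. GATA2 averaged 8.54 ± 0.02 (SD, n = 2) with H2O and 8.47 ± 0.08 (n = 2) with DMSO in LNCaP. None of the 24 lists was called by camera (adjusted p from 0.254 to 0.971), nor was any of their members over all genes. Adjusted over the list alone, 2 basal or mesenchymal markers were called higher with DMSO, PLAUR (0.65) and CXCL8 (0.36), and 1 lower, ITGA3 (-0.52), with 0 in the other lists. The fry test called that list for a change in either direction (adjusted p = 1.9e-04), and with it the ATF4 stress (0.0024) and cholesterol (0.0479) lists. The simulated changes of 1 on the log2 scale were recovered for 91.0% of genes in this comparison, and those of 0.5 for 41.8%. Many genes were changed at once in that simulation, which loosens the cut-off, so these shares overstate the recovery of few real vehicle differences. Within each line, changes as large as 1.22 were not called.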

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

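Results were picked out where a test of the difference between the lines' responses, or of probes outside the main measurement, was called. Other counts stand here only for the tests of chance and of run differences. The tests of a difference between labelling or hybridisation runs were chosen only after the result was seen. The other tests of explanations were written down before.

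Chance as the source of the gene counts was tested by splitting the arrays in other ways, with the vehicles merged. In LNCaP, 1 of 35 splits of the arrays, the real one, called as many genes (5365, against at most 2252 in another split), and in LNCaP-abl also 1 of 35 (6108 against 3188). For the difference of responses, 1 of 100 labellings, the real one, gave as many (4213 against at most 2032 in a drawn relabelling). For the controls of the lines it was 1 of 35 splits (5964 against 0). The real grouping called the most genes for all 4 counts. The smallest share that these tests could reach was 1 of 35, or 1 of 100 for the difference of responses. They argue against chance only to that extent, and only for these arrays, whose replicates may be technical.

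The cell cycle lists were picked out because their fall was deeper in LNCaP-abl, with a median difference of -2.09 for G2/M genes and -2.08 for G1/S genes. A background floor that hides part of the fall in LNCaP needs members without signal there, but 95.5% of the G2/M members were above background on all LNCaP dilazep arrays. On all LNCaP-abl dilazep arrays 29 of 44 members were above background, so the size of the difference is less certain for the rest. A higher start in LNCaP-abl with a common end level needs equal levels with dilazep, but the level in LNCaP-abl minus that in LNCaP had a median of -2.07 (quartiles -2.53 and -1.52, 44 of 44 members lower). Quantile normalization as the source was tested with median scaling, which left a median difference of -2.35, or -2.13 relative to all genes, while the size was smaller with the authors' processed values (-0.90 for G2/M and -1.14 for G1/S) and without background correction (-1.19 and -1.28), with both lists still called. A stronger arrest of proliferation in LNCaP-abl, whether from the line or its charcoal-stripped serum, may account for the pattern, as a hypothesis that these data do not test and that cell cycle profiles, with LNCaP in stripped serum as well, would decide.

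The ATF4 stress list was picked out because its genes rose in LNCaP-abl and had a median change of -0.06 in LNCaP, a median difference of 1.01. Median scaling left the list called (adjusted p = 6.9e-20, median 0.77, or 0.99 relative to all genes), and so did leaving out LNCaP dilazep replicate 4, at one end of its group on the third principal component (adjusted p = 2.1e-20). A higher start in LNCaP that leaves no room to rise was argued against by control levels, which had a median difference (LNCaP minus LNCaP-abl) of -0.13, with 4 of 36 members at least 0.5 higher in LNCaP. The unfolded protein response list, which bears on ER stress, was not called by camera in the difference of responses (9 members more positive, 6 more negative, adjusted p = 0.117). The fry test by direction, which sets no list against other genes, called it more positive (adjusted p = 1.3e-04). ER stress is therefore neither shown nor spoken against. What sets off the stress genes in LNCaP-abl was not tested, and the line and its serum both stay open.

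The number of genes whose response differed, 4056, is 33.8% of those tested. A difference between labelling or hybridisation runs that shifted each gene equally on the log2 scale in both lines cannot be the whole source. An equal effect on the signals can still give unequal log2 changes after background correction and normalization, where starting levels differ. The simulated data (10 false calls in this comparison) held no run difference and cannot say how many genes that would give. Of the 2939 genes that changed the same way in both lines, 1000 also differed in size. They were chosen by that call and add no separate evidence. For the G2/M list, control levels differed between the lines by a median of 0.15, yet 42 of 44 members were more negative in LNCaP-abl. That argues against a run difference alike in both lines as the whole source for this list. For 4034 genes called with dilazep in a line and not in the difference of responses, such a run difference and dilazep cannot be told apart, because no chip or run is named for any array (1939 were called the same way in both lines, 950 in LNCaP and not in LNCaP-abl, and 1145 the other way round). A run or experiment difference that acted differently in each line was not tested and stays open for every change with dilazep and every difference of responses, since the controls may come from a separate experiment.

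Other differences between the lines' responses are given as values. The MYC and ribosome biogenesis list had a median difference of -0.70, with BOP1 at -0.97, MYC at -1.28, PA2G4 at -1.02 and FBL at -0.97. Positive differences were those of TRIM49D1 (4.00), TRIM49D2 (3.91), MMP10 (3.85), CCL20 (3.79), TRIM49C (3.61) and SLC7A11 (3.55). Negative ones were those of MCM10 (-4.14), ANGPT2 (-4.04), DTL (-3.96), AURKB (-3.88), CDC45 (-3.85) and NCAPG (-3.77). Of the genes named throughout, GATA2 differed by -0.99, HOXB13 by -1.26, KLK3 by -1.25, KLK2 by -2.33 and SLC29A2 by -0.51. Further cell cycle genes were GINS2 (-3.52), TK1 (-3.48), CDCA3 (-3.32), UBE2C (-2.80), TTK (-2.58) and CDC20 (-2.56), and further stress genes were CTH (2.97), CHAC1 (2.78), ATF3 (2.27) and SLC7A5 (1.63). Other probes gave -1.31 for MCM10, 1.21 and 1.92 for CTH, 0.08 for UBE2C and -0.46 for MYC. Some of these differences rest on a level not above background and have no rank. This was the level in LNCaP-abl with dilazep for DTL, AURKB, CDC45 and KLK3, and in LNCaP with dilazep for CHAC1 and SLC7A5. It was every LNCaP-abl level for ANGPT2 and TRIM49D2, every LNCaP level for CCL20, and LNCaP with dilazep and the LNCaP-abl controls for MMP10. Of 8958 kept probes without a single gene symbol, which the gene comparisons do not use, 1611 were called with dilazep in LNCaP and 1753 in LNCaP-abl.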

How the results depend on the processing

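All alternatives were chosen before the data were examined. With a log2 change of at least 1 required, the counts of genes were 866 in LNCaP, 1447 in LNCaP-abl, 1182 for the difference of responses and 1235 between the lines, a stricter threshold by construction. The replicate number as a block called 3237 genes in LNCaP and 2302 for the difference of responses, and changed no other gene count by over 1.5 times. LNCaP dilazep replicate 4 is the only LNCaP array with its number. The block fits it exactly, which takes it out of both comparisons and leaves fewer residual degrees of freedom. In LNCaP-abl, where every number is shared, 5803 genes were called. The lower counts therefore cannot be read as an effect of the replicate numbers. The replicate numbers do not pair the arrays: the 8 same-number pairs within a line, which the block joins, had correlations of -0.18 to 0.05, the 14 across the lines -0.11 to 0.21, and 1 of 13 arrays correlated best with its own number in its line. All other settings stayed within 1.5 times, at 4253 to 5702, 4878 to 6270, 2846 to 4476 and 4087 to 6193 genes in the same order, and the vehicles differed in 0 genes throughout. Leaving out each array gave 4493 to 5274, 5439 to 6160, 3423 to 4036 and 5254 to 5978 genes. Of 24 lists, 8 were called in LNCaP, 9 in LNCaP-abl, 4 for the difference of responses, 3 between the lines and 0 between the vehicles. The fry test by direction called 17, 23, 18, 23 and 0, and in either direction 24, 24, 23, 24 and 3, as it sets no list against other genes. For the difference of responses, the authors' processed values and no background correction each called 8 lists (the cause was not tested). Between the lines, an estimated correlation left 1 list. Between the vehicles, the androgen-repressed list was called with only the arrays of the comparison (1 list), without LNCaP dilazep replicate 4 (1 list) and, with the hypoxia list, without LNCaP-abl DMSO replicate 1 (2 lists), a range of 0 to 2. In the difference of responses, CLDN8 (1.16) turned to -0.016 with the authors' processed values (adjusted p = 0.904). SYT4 (-1.51) turned to 0.50 with them (adjusted p = 6.9e-04) and 0.050 without background correction (adjusted p = 0.772). The cause was not tested. Leaving aside the minimum log2 change, 92 of the 102 called named genes kept their call under each alternative that tested them in LNCaP, 95 of 103 in LNCaP-abl, 81 of 96 for the difference of responses and 96 of 104 between the lines. The stricter filter tested only 65, 63, 59 and 59 of them. Among lists not called, the most alternatives gave a call to GATA2 and its partners in LNCaP-abl (15 of 30, adjusted p from 8.4e-11 by fry to 0.104), hypoxia in the difference of responses (10 of 29) and lysosome genes between the lines (8 of 30). Both fry tests are among the calls of the GATA2 list in LNCaP-abl, and that list shares FOXM1 with the G2/M list and MYC with the MYC list. Signal over background limits low genes. Without background correction the changes of the called named genes were smaller, with a median ratio of 0.739 to 0.780 by comparison. Whether low genes shrank most was not tested. The chip as a block was not run, because no chip is named.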

Other observations

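No test in this part was chosen after its result was seen. The lists given here were not called with dilazep in the line whose counts are given, so the counts describe their members alone. Genes of the unfolded protein response list went both ways. Of 22 measured members, 7 rose and 7 fell in LNCaP, and 11 rose and 6 fell in LNCaP-abl (adjusted p = 0.964 and 0.191). HSPA5, the main ER chaperone, rose by 1.20 in LNCaP and 2.36 in LNCaP-abl, while the transcription factor gene XBP1 changed by -1.02 in LNCaP. Of 16 adenosine transport and signalling genes, the group nearest to the known action of dilazep, 3 rose and 3 fell in LNCaP and 1 rose and 4 fell in LNCaP-abl (adjusted p = 0.964 and 0.0948). The deoxycytidine kinase gene DCK changed by -1.80 in LNCaP (-0.51 at its other probe) and -1.22 in LNCaP-abl. The adenosine receptor gene ADORA2B changed by -1.31 in LNCaP and was at least 3.23-fold lower in LNCaP-abl. Calcium genes had 8 rises and 2 falls among 23 members in LNCaP and 6 and 2 in LNCaP-abl (adjusted p = 0.0802 and 0.489). The calcineurin regulator RCAN2 was at least 1.48-fold and 3.65-fold higher. Of 31 hypoxia and glycolysis genes, 8 rose and 6 fell in LNCaP, and 8 rose and 15 fell in LNCaP-abl (adjusted p = 0.964 and 0.170). In LNCaP-abl PFKFB3 changed by -2.71 (-1.42 at its other probe) and PFKP by -1.58. Of 27 p53 targets, 9 rose and 5 fell in LNCaP and 14 rose and 4 fell in LNCaP-abl (adjusted p = 0.964 and 0.123), with TP53INP1 at 1.13 and 1.24 and DDB2 at -0.97 in LNCaP. The ATF4 stress list had 8 rises and 14 falls in LNCaP (adjusted p = 0.137), with DDIT3 at 1.20 and STC2 at -0.91.

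Oxidative phosphorylation genes (39 measured) had 3 rises and 7 falls in LNCaP and 7 and 16 in LNCaP-abl (adjusted p = 0.0802 and 0.228). Interferon response genes (29) had 7 and 7, and 10 and 4 (adjusted p = 0.964 and 0.371), with ISG20 at 1.20 in LNCaP-abl. Heat shock genes (21) had 3 and 2, and 4 and 10 (adjusted p = 0.964 and 0.172). Luminal markers (22) had 8 and 4, and 12 and 4 (adjusted p = 0.964 and 0.127). The protease gene PRSS8 was at 1.17 and 1.94, and keratin KRT19 was at least 4.40-fold and 1.89-fold lower. Basal and mesenchymal markers (15) had 3 and 3, and 7 and 2 (adjusted p = 0.964 and 0.181), with the chemokine gene CXCL8 at 2.45 in LNCaP-abl (4.44 at its other probe). Neuroendocrine markers (10) had 2 and 2, and 4 and 2 (adjusted p = 0.964 and 0.801), with EZH2 at -0.60 and -1.72 (other probes -1.40 and -1.26 in LNCaP). Fibroblast markers (6) had 2 and 1, and 1 and 2 (adjusted p = 0.964 and 0.655). Immune markers (8) had 2 and 1, and 4 and 0 (adjusted p = 0.520 and 0.361). The 1 measured endothelial marker, VWF, changed by -1.82 and -0.89 (adjusted p of the list 0.0802 and 0.228). The median, mean and test of a list differed in sign for 6 lists in LNCaP, 1 in LNCaP-abl, 3 for the difference of responses, 3 between the lines and 6 between the vehicles, and for 0 of the called lists.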
